A study of Mus musculus with 3 samples.

How the data were processed

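Mouse thymocyte RNA was measured on 3 spotted 2-colour arrays of one print, per the labels, each carrying CD69hi wild-type RNA against unseparated Zap70-/- RNA, with Cy3 on the CD69hi RNA on arrays 1 and 2 and Cy5 on array 3. The values deposited by the authors are 1 log ratio per probe and array. They are taken here as log2 values. The base is not given in the sources used here. The values reach -9.40, which as log10 would lie beyond a scanner's range, but a natural logarithm is not excluded, and then the fold changes would be larger. The deposited log2 ratios were centred near 0 on each array (medians -0.004, -0.005 and -0.002), and no value was missing. Background correction, spot filtering and normalization are not given in the sources used here. No spot intensities were used, so dim spots could not be left out. Ratios above 4 or below -4 occurred on 47, 29 and 30 probes of the 3 arrays and may come from dim spots, whose ratios are imprecise.

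Of 9596 probes, 7486 had 1 gene symbol in the platform annotation table, 483 had several and 1627 had none there. The Entrez identifiers of 7395 of the 1-symbol probes were found in the RefSeq gene table (GRCm38.p6), which changed 0 symbols, and the other 91 kept their symbol. Probes with 1 symbol were averaged per symbol and other probes stood alone, which gave 8905 features, 6795 of them genes. Of the symbols, 631 had more than 1 probe. Among these, 34 were called, and in 5 (Cd160, Gpld1, Gpr83, Gsdmc2, Tubgcp4) the probes' means spanned more than 1 on the log2 scale, with both signs in 2 (Gpld1 and Gsdmc2). Spotted cDNA probes can also bind transcripts of related genes, so values of multigene families such as Gimap, Slfn, Ly6, Ms4a and Klr are uncertain. Coordinates are not given because the probes carry no genome build.

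The values of arrays 1 and 2 were multiplied by -1 so that all ratios read CD69hi over Zap70-/-, with the deposited value read as Cy5 over Cy3. The design fixed before the data were examined required r under -0.3 between array 3 and both other arrays for this step and no direction otherwise. One pair missed the bound (r = -0.25). The turning was kept because the labels state the dye swap, which departs from that rule, and the fit without it is given as an alternative added after seeing the data. The direction followed the preset fallback of Rag1 and Dntt, since Cd69, Zap70 and Rag2 were not analysed here.

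Each feature was fitted with limma 3.58.1 (lmFit, eBayes) in R 4.3.3 with 1 coefficient and no dye term, leaving 2 residual degrees of freedom, to which eBayes added 2.75. P-values were two-sided and Benjamini-Hochberg adjusted over 8905 features, with 0.05 as the threshold. A ± gives the SD over the 3 arrays. A dye term in a second fit was called for 0 features (limma, 2161 at an unadjusted p of at most 0.05). Its median absolute size was 0.19, against 0.25 for the turned ratio in that fit. That fit leaves 1 residual degree of freedom, so the absence of calls does not exclude a dye bias. With 2 arrays in 1 orientation and 1 in the other, part of any dye bias stays in the reported ratios. On simulated data with the spread of this comparison (5 simulations of 8905 features), the fit recovered 15.0% of changes of 1 on the log2 scale and 83.2% of changes of 2, and 14 of 505 calls were false, so a gene that did not pass is not thereby unchanged. The simulated features varied independently, few of them were changed and no dye bias was added. These rates may therefore not hold for the real arrays.

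Before the data were examined, 23 gene lists were written. One, of Cd69 and Zap70, had 0 measured members. The other 22 were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. In simulation, a list of shifted genes was found in 5 of 5 runs and an unshifted one was called in 0. The simulated genes varied independently, so these runs do not show that camera's p-values hold for correlated lists. Estimated correlations ran from -0.08 (erythroid) to 0.71 (ribosomal proteins), with 0.21 for the early response and 0.60 for the cell cycle. None of the 10 camera calls held with an estimated correlation, which rests on 2 residual degrees of freedom. The lists overlap, so a gene can count in several. Genes were named by a rule set beforehand: the 12 highest and the 12 lowest called genes with one sign on every array, and in each list up to 4 called members with the largest ratios or, where none passed, 2 with the largest moderated t. Outside this rule, Cd160, Gpld1, Gsdmc2 and Tubgcp4 are named only because their probes differed. Other genes are named outside the rule as well, after their values were seen. These are Rag1 and Dntt for the direction, and Ly6e, Ifngr1, Pim1, Gata3, Runx3, Bcl2, Gpr83, Cd4, Cd8a, Cd3e, Ccnd1, B2m, Hspa1a, Cd79a, S100a8, Xist, Eif2s3y, Kdm5d, Nr3c1, Tsc22d3, H2-Ob, Ciita, H2-DMb1, Ctsh, Ctsd, Ctsb, C1qa, C1qb, C1qc, Itgb2 and Icam1. Alternatives were median centring, scaling, a dye term, array weights, 1 feature per probe, other thresholds, robust or no variance shrinkage, and leaving out each array. Figures were drawn with matplotlib 3.10.9.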

Results

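Thymocytes that receive a T cell receptor (TCR) signal during positive selection raise the surface protein CD69, and mice without the kinase Zap70 lack this signal, so their thymus holds few cells past the immature CD4+CD8+ (double-positive) stage. On 3 spotted 2-colour arrays, total RNA of purified CD69hi thymocytes from wild-type C57BL/6 mice was hybridised together with RNA of unseparated Zap70-/- thymocytes. The titles name the second RNA CD69lo, and the comparison asks which transcripts differ between signalled and unsignalled thymocytes. Genotype and purification also differ between the 2 RNAs, and the stages and kinds of cells in them and the sex of the mice may differ. No ratio can therefore be assigned to the TCR signal alone. The CD69hi RNA carried Cy3 on arrays 1 and 2 and Cy5 on array 3. The labels do not say whether the arrays came from separate mice, so the p-values measure only the spread between these arrays, which may be technical. Each array gave a log ratio for 9596 probes. Their number, 3, and not a read depth, limits the precision.

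The deposited ratios were read as running by dye. Before any turning, the ratios of array 3 correlated negatively across all probes with those of array 1 (Pearson r = -0.25) and of array 2 (r = -0.40), while arrays 1 and 2 correlated positively (r = 0.61). Genes are not independent replicates, and these values describe the arrays. The bound set beforehand for calling the table unturned (r under -0.3 with both arrays) was missed by array 1. In the 2227 features with the largest absolute ratios r was -0.32 and -0.48, but choosing large ratios itself raises the size of a correlation, so this is no independent support for turning. The bound would have left the direction open, so turning departs from it. The ratios were turned by the labelled dyes and are given as CD69hi over Zap70-/-. This direction is likely but not stated by the submitters. It rests on the TCR recombinase gene Rag1, which had a log2 ratio of -1.19 ± 0.36 (SD, n = 3), and on the terminal transferase gene Dntt, at -1.05 ± 0.71 (SD, n = 3), which did not pass (limma adjusted p = 0.12). Both belong to immature thymocytes. Rag1 passed (adjusted p = 0.035), but not without array 1 (adjusted p = 0.13) or array 2 (adjusted p = 0.18). Probes for Cd69 and Zap70 were not analysed here, so neither the sort nor the deletion was checked. Of genes not used to set the direction, and looked at after their values were seen, Cd5 (4.75 ± 0.43) and Nr4a1 (3.78 ± 0.06), both induced by TCR signals, lay above 0 on every array in this reading. Of 31 TCR-induced genes 21 rose and 1 fell. With the opposite reading every sign would turn.

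Of 8905 features, 618 differed between the 2 RNAs at an adjusted p of at most 0.05 (limma, Benjamini-Hochberg). Of these, 368 were higher and 250 lower in CD69hi cells, with median log2 ratios of 1.18 and -1.18. All 618 had one sign on the 3 arrays, which passing this threshold with 3 arrays itself requires, so it is no separate support. At least a 2-fold difference on every array was reached by 253 features, 168 higher and 85 lower. With array 3 left unturned the fit called 0 features (342 at an unadjusted p of at most 0.05) and 12 features exceeded 2-fold on every array. The sex-linked RNAs measured also differed. Xist, which is transcribed from the inactive X chromosome of female cells, was 3.57-fold higher in CD69hi RNA (limma adjusted p = 0.044), and the Y-linked genes Eif2s3y and Kdm5d were 3.06-fold and 2.97-fold higher in Zap70-/- RNA (adjusted p = 0.040 and 0.041). Xist, Eif2s3y and Kdm5d did not pass without array 2 (adjusted p = 0.13 each) or array 3 (adjusted p = 0.10, 0.076 and 0.094). Xist and Kdm5d did not with a dye term (adjusted p = 0.060 and 0.067), nor Kdm5d with scaling (adjusted p = 0.052). Among markers of other cells, 15 of 31 macrophage, dendritic cell and granulocyte genes rose and 2 fell. A granulocyte list drawn up after the first results had a median log2 ratio of -0.86, so granulocyte genes did not rise as a group. The counts depended on the arrays used, with 201 calls without array 1, 119 without array 2 and 692 without array 3. Without array 3 the CD69hi RNA carried Cy3 on every array left, so a dye bias cannot be told apart from the ratio there. Each of these fits also has fewer residual degrees of freedom, so a lost call can reflect lost power.

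**Figure D1:**
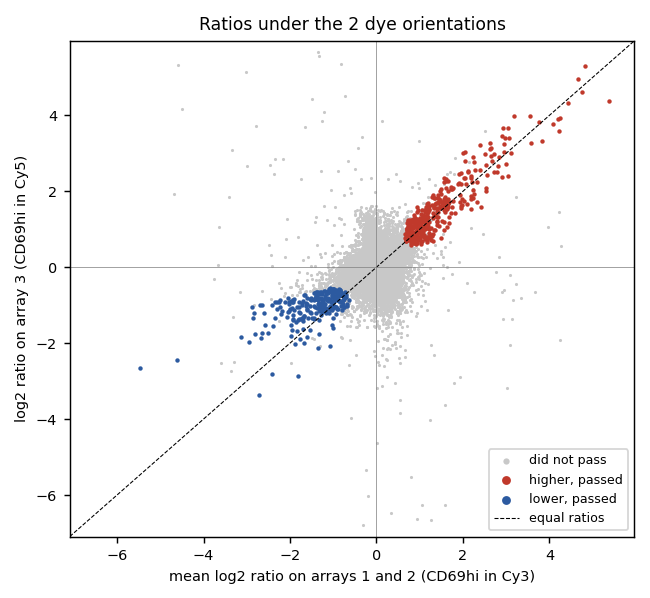
Each point is 1 of 8905 features, with the mean log2 ratio of CD69hi over Zap70-/- on arrays 1 and 2 on the x axis and the log2 ratio on array 3, of the opposite dye orientation, on the y axis. The 368 features called higher lie along the line of equal ratios, while the 250 called lower lie mostly nearer 0 on array 3, with medians of -1.24 and -1.37 on arrays 1 and 2 and -0.92 on array 3.

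The 12 genes with the highest ratios included TCR-induced genes, genes listed for maturation after selection and a lineage regulator. In the same RNA 15 of 31 macrophage, dendritic cell and granulocyte genes rose and 2 fell. Whether thymocytes were the source of all 12 transcripts was not tested. Nr4a3 and Nr4a1, orphan nuclear receptors induced by TCR signals, had log2 ratios of 5.05 ± 2.24 (SD, n = 3, adjusted p = 0.041) and 3.78 ± 0.06 (adjusted p = 0.0051). Cd5, a surface inhibitor of TCR signalling, was 27.0-fold higher (log2 ratio 4.75 ± 0.43, adjusted p = 0.0051). Zbtb7b, which encodes the CD4-lineage factor ThPOK, was 8.99-fold higher (log2 ratio 3.17 ± 0.59, adjusted p = 0.010). The chemokine receptor Ccr7 (3.25 ± 0.44), the tetraspanin Cd53 (3.17 ± 0.23) and Ms4a4b (3.47 ± 0.29) rose as well. The other 5 of the 12 highest were Socs4 (3.69 ± 0.25), the creatine kinase Ckb (3.45 ± 0.68), the epoxide hydrolase Ephx1 (3.08 ± 0.40), the chemokine Ccl22 (3.07 ± 0.37) and Nnmt (3.05 ± 0.26). Nr4a3 was the 1 gene of these 12 whose call ended in a leave-one-out fit (adjusted p = 0.090 without array 3). Its call also ended with scaling (adjusted p = 0.058), with a dye term (adjusted p = 0.075) and with robust shrinkage (adjusted p = 0.088).

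Among the 12 lowest, Kifap3, a kinesin-associated protein, had a log2 ratio of -4.54 ± 1.65 (SD, n = 3, adjusted p = 0.030) and the aspartic protease Ctse -2.94 ± 0.44 (adjusted p = 0.0089). Fkbp5, a co-chaperone of the glucocorticoid receptor, followed at -2.71 ± 0.75, the amino acid transporter Slc43a1 at -2.63 ± 0.57, the lysosomal protease Ctsl at -2.54 ± 0.63 and Desi1 at -2.47 ± 0.61. The DNA repair subunit Xrcc6 (-2.41 ± 0.47), Ly6d (-2.35 ± 0.88), the retinol dehydrogenase Dhrs3 (-2.34 ± 0.53), the granzyme Gzma (-2.29 ± 0.94), the cyclin Ccnf (-2.27 ± 1.05) and Hmcn1 (-2.24 ± 0.46) completed this group. Of these 12 genes, 7 passed in all 3 leave-one-out fits. Kifap3, Ly6d, Gzma and Ccnf did not pass without array 1 (adjusted p from 0.056 to 0.13), Ly6d, Gzma and Ccnf did not without array 2 (adjusted p from 0.073 to 0.12), and Ctsl did not without array 3 (adjusted p = 0.054). With scaling, Gzma and Ccnf did not pass (adjusted p = 0.052 and 0.062).

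**Figure D2:**
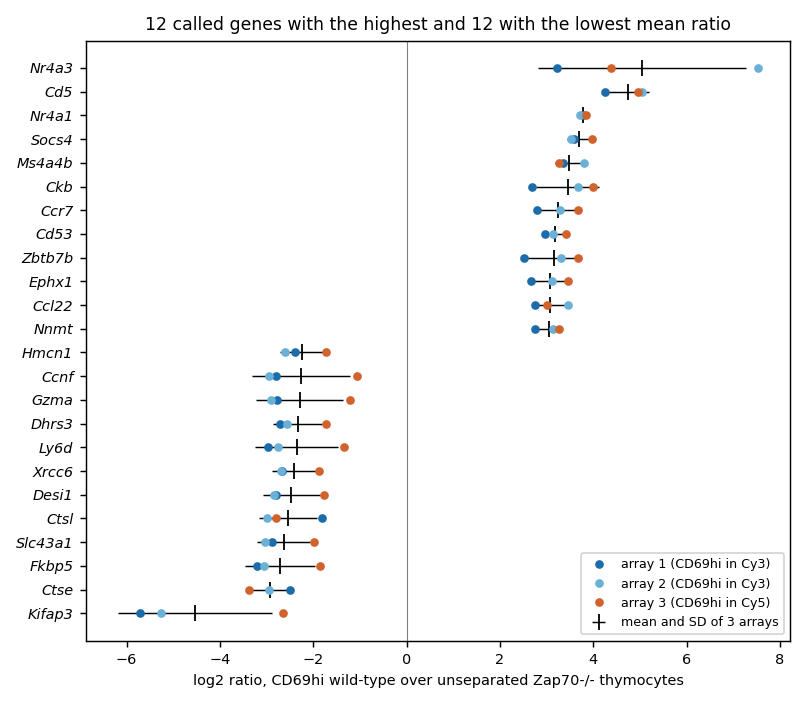
Log2 ratios of CD69hi over Zap70-/- thymocytes on each of the 3 arrays (points) with the mean and SD (line) for the 12 called genes with the highest and the 12 with the lowest mean. Nr4a1 differs least between arrays (SD 0.06) and Nr4a3 most (SD 2.24), while 10 of the 12 lowest genes are nearest 0 on array 3.

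Of 31 measured genes of the TCR-induced early response, 21 rose, 1 fell and 9 did not pass, and the list median was 1.57. When the p-values were adjusted over the list alone, 25 rose and 3 fell. Besides Nr4a3, Nr4a1 and Cd5, the risers included Nab2, a co-repressor of the Egr factors, at a log2 ratio of 2.98 ± 0.44 (SD, n = 3). The kinase gene Pim1 fell (-1.25 ± 0.33), but not without array 1 (adjusted p = 0.11) or array 2 (adjusted p = 0.15). The list differed from the other genes by camera (adjusted p = 1.6e-14). Its call was lost with an estimated correlation (adjusted p = 0.43). Without array 2, 13 of its genes rose.

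Of 25 lineage transcription factors, 8 rose, 5 fell and 12 did not pass, with a median of 0.08, and the counts were the same adjusted over the list alone. Zbtb7b rose together with the E protein inhibitor Id2 (2.81 ± 0.42, SD, n = 3), the selection-associated factor Tox (2.65 ± 0.16) and Klf2 (2.43 ± 0.34), a factor of T cell egress. Gata3, required for the CD4 lineage, rose as well (1.61 ± 0.10), but did not pass without array 2 (adjusted p = 0.052). The CD8-lineage factor Runx3 did not pass (0.52 ± 0.33, adjusted p = 0.17). The list did not pass camera (adjusted p = 0.15), except without array 2 (adjusted p = 0.046), and passed fry's directional test, which makes no comparison with other genes (adjusted p = 0.0078). Without array 1 the counts were 7 rising and 1 falling, and without array 2 they were 4 and 0, and without array 3 they were 8 and 3.

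Of 33 genes of maturation and survival after selection, 16 rose, 2 fell and 15 did not pass (median 0.73), or 24 and 4 adjusted over the list alone. Ms4a4b, Ccr7, Cd53 and the Schlafen gene Slfn1 (2.78 ± 0.33, SD, n = 3) led the list. The 2 that fell were Ly6e (-1.13 ± 0.44) and the interferon-γ receptor gene Ifngr1 (-1.12 ± 0.41). Neither passed without array 1 (adjusted p = 0.17 each), without array 2 (adjusted p = 0.24 and 0.23) or with scaling (adjusted p = 0.063 and 0.059). Bcl2, an anti-apoptotic gene, had a log2 ratio of 0.40 ± 0.38 and did not pass (adjusted p = 0.28), although 1 of its probes did when fitted alone (adjusted p = 0.018). The list passed camera (adjusted p = 6.3e-11). Its call was lost with an estimated correlation (adjusted p = 0.55). In this RNA 15 of 31 macrophage, dendritic cell and granulocyte genes also rose and 2 fell. Thymocytes may therefore not be the only source of the maturation transcripts, which was not tested.

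Chemokine receptors, adhesion and migration genes rose in 11 of 25 cases and fell in 2, with 12 not passing (median 0.57), and adjusted over the list alone 13 rose and 4 fell. Beside Ccr7 and Klf2, the integrin chain Itgb7 (2.25 ± 0.30, SD, n = 3) and the hyaluronan receptor Cd44 (2.15 ± 0.33) rose. Myeloid cells also express Cd44 and 2 other risers, Itgb2 (1.40 ± 0.23) and Icam1 (1.49 ± 0.08). In the same RNA 15 of 31 macrophage, dendritic cell and granulocyte genes rose and 2 fell. The list's camera call (adjusted p = 0.0038) was lost with an estimated correlation (adjusted p = 0.68), without array 3 (adjusted p = 0.088) and in fry's directional test (adjusted p = 0.059). Without array 2, 5 of its genes rose, and Itgb2 and Icam1 did not pass (adjusted p = 0.084 and 0.062). Of 25 cytokine receptor and JAK-STAT genes, 7 rose, 3 fell and 15 did not pass (median 0.23), or 8 and 4 adjusted over the list alone. Il7r, the receptor of the survival cytokine interleukin-7, rose 6.77-fold (log2 ratio 2.76 ± 0.22, adjusted p = 0.0057), and Il2rb (1.82 ± 0.76) and Il27ra (1.45 ± 0.20) rose too. Socs3, an inhibitor of cytokine signalling, fell (-1.93 ± 0.20). Il2rb did not pass without array 2 (adjusted p = 0.13), without array 3 (adjusted p = 0.089) or with a dye term (adjusted p = 0.051), and Il27ra did not without array 2 (adjusted p = 0.067). This list did not pass camera (adjusted p = 0.11). The number rising was 3 without array 1, 1 without array 2 and 3 without array 3.

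Of 29 genes listed for immature double-positive thymocytes, 9 fell, 3 rose and 17 did not pass (median -0.55), and adjusted over the list alone 16 fell and 5 rose. Rag1 and Dntt, which set the direction, are members, so the list is no independent evidence of it. Ly6d and the aquaporin Aqp11 (-2.11 ± 0.48, SD, n = 3) fell furthest. The 3 that rose were Tox, the sialyltransferase St6gal1 (2.38 ± 0.33) and Gpr83, whose 2 probes differed by 1.12 on the log2 scale. Gpr83 did not pass without array 2 (adjusted p = 0.14), without array 3 (adjusted p = 0.092) or with a dye term (adjusted p = 0.057). The camera call (adjusted p = 3.0e-04) was lost with an estimated correlation (adjusted p = 0.68). It was also lost in fry's directional test (adjusted p = 0.14). The number falling was 3 without array 1 and 2 without array 2.

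Of 29 genes of the TCR complex and its proximal signalling, 4 rose, 2 fell and 23 did not pass (median 0.04), or 8 and 5 adjusted over the list alone. Cd5, its relative Cd6 (2.59 ± 0.12, SD, n = 3) and the Src kinase Fyn (1.57 ± 0.16) rose and the Tec kinase gene fell (-1.59 ± 0.36). Fyn did not pass without array 2 (adjusted p = 0.060), nor Tec without array 1 (adjusted p = 0.070) or array 2 (adjusted p = 0.077). The coreceptor genes Cd4 (-0.29 ± 0.07, adjusted p = 0.25) and Cd8a (-1.13 ± 0.62, adjusted p = 0.081) and the CD3 chain Cd3e (-0.21 ± 0.11, adjusted p = 0.40) did not pass. Cd8a passed without array 3 (adjusted p = 0.043) and with a dye term (adjusted p = 0.048). The list did not pass camera (adjusted p = 0.30), and the counts were 3 rising and 0 falling without array 1, 2 and 1 without array 2, and 3 and 3 without array 3.

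Of 64 cell cycle and DNA replication genes, 22 fell in CD69hi RNA, 2 rose and 40 did not pass (median -1.08), and adjusted over the list alone 55 fell and 2 rose. The mitotic kinase genes Bub1b (-2.14 ± 0.81, SD, n = 3), Aurkb (-1.95 ± 0.83) and Cdk1 (-1.87 ± 0.82) fell. The 2 that rose were the D-type cyclins Ccnd2 (2.67 ± 0.84) and Ccnd1 (0.81 ± 0.10). The 3 kinase genes did not pass without array 1 (adjusted p from 0.095 to 0.13) or array 2 (adjusted p from 0.083 to 0.13), nor Aurkb and Cdk1 with scaling (adjusted p = 0.056 and 0.059). Ccnd2 did not pass without array 3 (adjusted p = 0.063), nor Ccnd1 without array 1 (adjusted p = 0.15) or array 2 (adjusted p = 0.28). The list median was -1.30 on array 1, -1.38 on array 2 and -0.69 on array 3. The camera call (adjusted p = 1.7e-21) was lost with an estimated correlation (adjusted p = 0.55) and in fry's directional test (adjusted p = 0.093). The number falling was 0 without array 1, 0 without array 2 and 44 without array 3, and 44 with a dye term.

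Few genes of the metabolic and housekeeping lists passed. Of 40 oxidative phosphorylation genes, 0 passed, also adjusted over the list alone (limma, 0 higher and 8 lower at an unadjusted p of at most 0.05), and 4 fell without array 3. The 40 had a median of -0.34, which was -0.60 and -0.46 on arrays 1 and 2 and 0.06 on array 3. Uqcr11 (-0.81 ± 0.53, SD, n = 3) and Ndufaf3 (-0.64 ± 0.34) had the lowest values. Uqcr11 passed without array 3 (adjusted p = 0.036) and with a dye term (adjusted p = 0.047). The list's camera call (adjusted p = 3.0e-04) was lost with an estimated correlation (adjusted p = 0.78) and in fry's directional test (adjusted p = 0.38). Of 28 ribosomal protein genes, 0 passed (median -0.08), also adjusted over the list alone (0 higher and 0 lower at an unadjusted p of at most 0.05), and the largest shifts were -0.36 ± 0.45 for Rps14 and -0.29 ± 0.36 for Rpl7. Their list median was -0.26 and -0.28 on arrays 1 and 2 and 0.28 on array 3. In glycolysis, Pfkfb3 rose (0.85 ± 0.23), the lactate dehydrogenase Ldhb (-0.98 ± 0.30) and the lactate transporter Slc16a1 (-1.75 ± 0.33) fell, and 9 of 12 genes did not pass (3 and 3 passed adjusted over the list alone). Without array 1, 1 glycolysis gene rose and 1 fell, without array 2 these counts were 0 and 0, and without array 3 they were 0 and 3. Pfkfb3 did not pass without array 1, 2 or 3 (adjusted p = 0.22, 0.23 and 0.062), with scaling (adjusted p = 0.054) or with a dye term (adjusted p = 0.052). Ldhb did not pass without array 1 (adjusted p = 0.18), without array 2 (adjusted p = 0.24) or with scaling (adjusted p = 0.054), nor Slc16a1 without array 2 (adjusted p = 0.055). Of 11 cholesterol synthesis genes 0 passed (median -0.24, 1 lower adjusted over the list alone, 0 higher and 2 lower at an unadjusted p of at most 0.05), with Hmgcs1 at -0.79 ± 0.24 and Fdft1 at -0.61 ± 0.27. Hmgcs1 passed without array 3 (adjusted p = 0.039) and with a dye term (adjusted p = 0.038). The glycolysis, ribosomal protein and cholesterol lists did not pass camera (adjusted p = 0.92, 0.34 and 0.10), but the latter 2 did without array 3 (adjusted p = 1.2e-04 and 0.018).

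Of 24 interferon response genes, 11 rose, 1 fell (Ly6e) and 12 did not pass (median 0.87), or 17 and 2 adjusted over the list alone. The regulator Irf7 rose 7.01-fold (log2 ratio 2.81 ± 0.18, SD, n = 3, adjusted p = 0.0051), and Ifit3 (1.94 ± 0.22), Irf9 (1.64 ± 0.50) and Oas1a (1.55 ± 0.49) rose too. Irf9 and Oas1a did not pass without array 2 (adjusted p = 0.096 and 0.12) or array 3 (adjusted p = 0.062 and 0.070). Macrophages and dendritic cells also express interferon response genes. In the same RNA 15 of 31 genes of the macrophage, dendritic cell and granulocyte list rose and 2 fell. The camera call (adjusted p = 1.9e-09) was lost with an estimated correlation (adjusted p = 0.43). The number rising was 5 without array 1 and 2 without array 2. Of 12 MHC class I and antigen processing genes, 0 rose (3 higher and 3 lower at an unadjusted p of at most 0.05), and the class I-like gene Mr1 fell (-1.18 ± 0.04), but not without array 1 (adjusted p = 0.081) or array 2 (adjusted p = 0.12). The class I light chain B2m had a log2 ratio of 0.73 ± 0.35 and did not pass (adjusted p = 0.093), except with a dye term (adjusted p = 0.0497). Adjusted over the list alone 2 rose and 2 fell, and the list did not pass camera (adjusted p = 0.96).

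Of 24 apoptosis genes, 3 rose and 3 fell (4 and 5 adjusted over the list alone, median -0.09, camera adjusted p = 0.92). Without array 1 the counts were 1 and 0, without array 2 they were 0 and 0, and without array 3 they were 3 and 4. The tumour necrosis factor receptor Tnfrsf1b (1.55 ± 0.06, SD, n = 3) and the adaptor Traf1 (1.21 ± 0.06) rose, and the pro-apoptotic Bid (-1.31 ± 0.41) and the anti-apoptotic Bcl2l1 (-0.99 ± 0.13) fell. Without array 2 none of these 4 passed (adjusted p from 0.056 to 0.20), and without array 1 Traf1, Bid and Bcl2l1 did not (adjusted p = 0.072, 0.12 and 0.13). Of 17 heat shock and handling stress genes, Gadd45b (2.14 ± 0.55) and Gadd45a (0.88 ± 0.22) rose, also adjusted over the list alone, and 15 did not pass, the heat shock gene Hspa1a among them (1.91 ± 1.31, adjusted p = 0.11), which passed without array 1 (adjusted p = 0.018). Gadd45a did not pass without array 1, 2 or 3 (adjusted p = 0.12, 0.25 and 0.0535), nor Gadd45b without array 1 (adjusted p = 0.053). That list did not pass camera (adjusted p = 0.37).

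Markers of other cell types differed too. Of 31 macrophage, dendritic cell and granulocyte genes, 15 rose, 2 fell and 14 did not pass (median 1.02), or 18 and 7 adjusted over the list alone. The protease Ctss (2.83 ± 0.41, SD, n = 3), lysozyme Lyz2 (2.51 ± 0.08) and Apoe (2.46 ± 0.14) rose, and Ctsl and the granulocyte gene S100a8 (-0.86 ± 0.27) fell. S100a8 did not pass without array 1, 2 or 3 (adjusted p = 0.18, 0.35 and 0.052), with scaling (adjusted p = 0.065) or with 1 feature per probe (adjusted p = 0.051). Camera called the list (adjusted p = 1.9e-05), and the call was lost with an estimated correlation (adjusted p = 0.43). Without array 2, 10 of its genes rose. Of 14 B cell list genes, 3 rose and 1 fell (6 and 1 adjusted over the list alone). The 3 were the MHC class II genes H2-Aa (2.39 ± 0.29) and H2-Eb1 (2.30 ± 0.14) and the invariant chain Cd74 (1.67 ± 0.18), which macrophages and dendritic cells also express, while Cd79a of the B cell receptor did not pass (1.40 ± 0.70, adjusted p = 0.062). That list's camera call (adjusted p = 0.0053) was lost with an estimated correlation (adjusted p = 0.52) and without array 3 (adjusted p = 0.088).

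Of 13 genes listed for NK, NKT and γδ T cells, 5 rose, 1 fell and 7 did not pass (9 and 1 adjusted over the list alone). Il2rb and the chemokines Xcl1 (1.31 ± 0.25, SD, n = 3) and Ccl5 (1.05 ± 0.24) were among the risers and Gzma fell. Xcl1 did not pass without array 2 (adjusted p = 0.12), nor Ccl5 without array 1 (adjusted p = 0.13) or array 2 (adjusted p = 0.21). Camera called this list (adjusted p = 0.0015), and the call was lost with an estimated correlation (adjusted p = 0.43). The number rising was 2 without array 1 and 0 without array 2. Of 13 genes of double-negative thymocytes, Cd44, Lmo2 (1.18 ± 0.08) and Spi1 (1.05 ± 0.34) rose and Notch3 fell (-1.67 ± 0.71), with the same counts adjusted over the list alone. Myeloid cells also express the 3 that rose. In the same RNA 15 of the 31 macrophage, dendritic cell and granulocyte genes, Spi1 among them, rose as well and 2 fell. Of these 13 genes, 1 rose without array 1, 1 without array 2 and 2 without array 3. Spi1 did not pass without array 1, 2 or 3 (adjusted p = 0.13, 0.25 and 0.056), with a dye term (adjusted p = 0.051) or with scaling (adjusted p = 0.058). Lmo2 did not pass without array 1 (adjusted p = 0.072) or array 2 (adjusted p = 0.13). Notch3 did not without array 2 (adjusted p = 0.12), without array 3 (adjusted p = 0.097), with a dye term (adjusted p = 0.074) or with scaling (adjusted p = 0.059). Of 26 epithelial and stromal genes, Igfbp4 rose (1.71 ± 0.24) and Ctsl fell, again with the same counts adjusted over the list alone, but Igfbp4 did not pass without array 2 (adjusted p = 0.053). Of 9 erythroid genes 0 passed, also adjusted over the list alone (2 higher and 1 lower at an unadjusted p of at most 0.05), with Tfrc at 0.74 ± 0.31 and Alas2 at 0.53 ± 0.21. These 3 lists did not pass camera (adjusted p = 0.55, 0.92 and 0.92), and their medians (-0.007, 0.08 and 0.05) differed in sign from their means (0.13, -0.04 and -0.01) and from camera's direction.

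**Figure D3:**
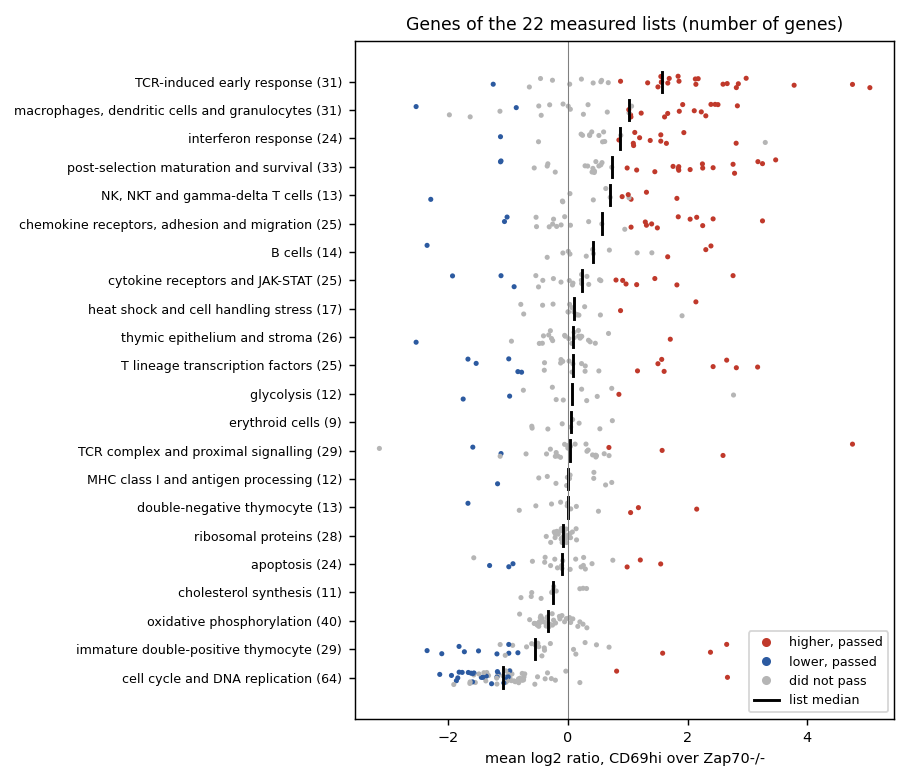
Mean log2 ratios of CD69hi over Zap70-/- for the genes of the 22 measured lists, ordered by list median (black bars), with red and blue points for genes that passed as higher or lower and grey for those that did not. Medians run from -1.08 for cell cycle genes to 1.57 for the TCR-induced early response.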

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

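All alternatives were chosen before the data were examined except the unturned array 3. The fit reported called 618 features. Centring (622 calls), scaling (502) and robust shrinkage (645) stayed within 1.5 times this count. A dye term gave 1076 calls (562 higher, 514 lower; 575 shared). Array weights gave 3657 (1826 higher, 1831 lower), resting mostly on array 2 (weight 4.56, against 0.93 and 0.23). Without variance shrinkage 0 passed (0 higher, 0 lower; 1731 at an unadjusted p of at most 0.05). With array 3 unturned 0 passed in either direction (limma, 342 unadjusted), 12 features exceeded 2-fold on every array and 4 lists passed. At adjusted p limits of 0.01 and 0.1, 59 (54 higher, 5 lower) and 1117 (603 higher, 514 lower) passed, and 2083 (1069 higher, 1014 lower) at an unadjusted p of 0.05. Leaving out 1 array gave 119 to 692 calls, 95 to 283 higher and 24 to 409 lower. These fits have fewer residual degrees of freedom, and the fit without array 3 cannot separate a dye bias from the ratio. Higher calls made up 84.1%, 79.8% and 40.9% without arrays 1, 2 and 3, against 59.6%. Of 70 called genes named by the rule, 38 passed in all 3 of these fits (29 of 46 higher, 9 of 24 lower). Limits of 1.5-fold and 3-fold gave 665 and 93 features on every array against 253, and leaving out 1 array gave 274 to 459. Correlations in the 2227 features with the largest absolute ratios were 0.626, 0.315 and 0.478 after turning. Of the lists, 10 passed camera, 0 with an estimated correlation, 7 by fry's directional test and 20 by its mixed test.

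The tested direction of some lists turned, with these medians. Of these lists, camera had called that of chemokine receptors and migration alone, which turned with array 3 unturned (0.178, not called). Bcl2, which did not pass, turned there too (-0.0568). So did TCR signalling (-0.125), glycolysis (-0.0823), heat shock (-0.106) and erythroid genes (0.20). Fry's directional test turned apoptosis (-0.0943), glycolysis (0.0747), erythroid (0.045) and stromal genes (0.0836). The dye term turned MHC class I (0.0201), ribosomal (0.0023) and stromal genes (0.0117), array weights MHC class I (0.0614) and heat shock (-0.0307), and 1 feature per probe stromal genes (0.103). Leaving out 1 array turned 7 lists, whose medians ranged from -0.0332 to 0.057 for MHC class I, -0.184 to 0.021 for apoptosis, -0.268 to 0.0132 for ribosomal, -0.178 to 0.112 for double-negative, 0.0475 to 0.165 for glycolysis, 0.039 to 0.237 for heat shock and -0.0343 to 0.079 for stromal genes. The cause was not tested. The planned filters on missing values and dim spots were not run, since no value was missing and no intensities were used.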

Other observations

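Of the tests in this part, those of macrophage RNA, of a dye bias in macrophage genes, of compression and of a dye effect on array 3, and of the sex-linked genes were chosen after the result was seen. MHC class II genes and cathepsins were grouped after their values were seen. Of 7 MHC class II genes 6 rose, of which H2-Aa, H2-Eb1 and Cd74 also stand in lists fixed beforehand. The others were H2-Ob at a log2 ratio of 1.62 ± 0.35 (SD, n = 3, limma adjusted p = 0.020), the class II transactivator Ciita at 1.15 ± 0.19 (adjusted p = 0.024) and H2-DMb1 at 0.93 ± 0.22 (adjusted p = 0.038). These 3 did not pass without array 2 (adjusted p = 0.067, 0.15 and 0.27), nor Ciita and H2-DMb1 without array 1 (adjusted p = 0.073 and 0.11), nor H2-DMb1 without array 3 (adjusted p = 0.064). Of 13 cathepsins, Ctsh (2.09 ± 0.32, adjusted p = 0.011) rose beside Ctss, Ctse and Ctsl fell and 9 did not pass. Ctss and Ctsl stand in the fixed lists too. The glucocorticoid receptor gene Nr3c1 fell (-1.80 ± 0.07, adjusted p = 0.0089), as did 2 genes induced by its hormone, Fkbp5 and Tsc22d3 (-2.10 ± 0.96, adjusted p = 0.047). Tsc22d3 did not pass without array 1 (adjusted p = 0.13), without array 2 (adjusted p = 0.12) or with scaling (adjusted p = 0.061).

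Of 16 macrophage and dendritic cell genes 11 rose (median log2 ratio 1.42), in lists by cell type drawn up after the first results were seen. A lower share of thymocytes would raise all other cell types alike. The granulocyte list, whose median of -0.86 lay 2.28 below that of the macrophage list (permutation test, two-sided, adjusted p = 7.8e-04), goes against such an equal rise. The erythroid, stromal and B cell lists had medians of -0.03, 0.08 and 0.31 (same test, adjusted p = 0.034, 3.6e-04 and 0.036). Dim spots could not be left out, so lists near 0 may hold undetected genes and cannot decide this. The permutations shuffled genes, which are not independent. Ctsl, which fell, and Spi1, which rose, stand in none of these lists. Nor do Ctsd (-0.45 ± 0.13) and Ctsb (0.004 ± 0.44) of the fixed macrophage list, which did not pass. The p-values therefore only describe the lists as drawn. On array 3 the list median was 1.03 times that on the other 2 arrays, so the rise was of like size in both dye orientations. This is no independent test of a dye bias, since called genes raised the question and all called genes had one sign on every array. RNA of macrophages and dendritic cells in the CD69hi fraction stays open: 6 of 6 abundant transcripts (Lyz2, C1qa, C1qb, C1qc, Apoe and Ctss) passed, but they are members of the list that raised the question, so this is no test of it. The purification of CD69hi cells would deplete such cells unless they passed it, its purity was not tested, and expression of these genes in the thymocytes also stays open.

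Genes lower in CD69hi RNA had smaller ratios on array 3, and 50 of 64 cell cycle genes lay nearer 0 there than on both other arrays. Compression of all ratios on array 3 is argued against by the 64 early response and maturation genes, whose median there was 1.10 times that on the other arrays (bootstrap 95% interval over genes 0.88 to 1.41). The cell cycle median on array 3 was 0.51 times the mean of the medians on arrays 1 and 2. A dye effect and a difference in that array's RNA cannot be told apart, since 1 array has that orientation.

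Xist was higher and the 2 measured Y-linked genes, Eif2s3y (-1.61 ± 0.64, SD, n = 3) and Kdm5d (-1.57 ± 0.62), were lower in CD69hi RNA, below 0 on every array. On array 3, of the opposite dye orientation, the smallest of the 3 genes' ratios was 1.08 times its mean on the other arrays. This is no independent test of a dye bias, since all 3 genes were called and called genes had one sign on every array. All 3 genes were nearest 0 on array 1. Xist was at 0.92 there, against 2.32 and 2.27 on arrays 2 and 3. Eif2s3y was at -0.90 against -1.80 and -2.13, and Kdm5d at -0.92 against -2.15 and -1.65. Why array 1 differed was not tested. A different mix of female and male mice behind the 2 RNAs stays open, since these genes raised the question and are no test of it. Whether sex contributed to other differences was not tested, and the design gives no groups by sex.

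The hypothesis that glucocorticoid targets were lower as a set was not borne out in the targets other than Fkbp5 and Tsc22d3. The other 13 measured targets had a median log2 ratio of 0.03 (quartiles -0.22 and 0.19), with 0 lower and 1 higher among them (camera with an estimated correlation, p = 0.85). Dim spots could not be left out, so some of these targets may be undetected, and a median near 0 cannot exclude the hypothesis.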
